A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

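The 4 libraries were single-read sequences of mononucleosomal DNA from Saccharomyces cerevisiae, 1 library each of wild type, a nup170 deletion strain and an Sth1 depletion strain at 0 h and 2 h. Per the labels' protocols, cultures in rich medium at an OD600 of 1.0 were fixed with 1% formaldehyde for 20 min and quenched with 125 mM glycine for 5 min, digested with micrococcal nuclease, and mononucleosomal bands were cut from a 2% agarose gel for Illumina sequencing. Groups were taken from the genotype label of each sample. The labels describe how the nup170 deletion was made by a marker replacement and do not say how Sth1 was depleted.

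The authors' deposited read files list 1 aligned read per line with its chromosome, strand, position and a count of 1, so a read count of a region is a number of lines and is not normalized. Positions, a unit of the kind other, are in bp on an unnamed build, as the deposited files give them. The deposited call files give nucleosome positions for each sample with a score from 3.00 upward, and what the score measures is not given in the sources used here, so it was used only to rank and match calls. Calls were made by the authors separately for each sample, per the file headers and names. The submitters' processing notes name CASAVA. Aligner settings, read length, the call program's settings, duplicate handling and the genome build are not given in the sources used here. PCR duplicates cannot be told from independent molecules, so intervals and floors cover counting error only.

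Coordinates are printed as in the files and were taken to start at 1. Gene names, lengths and chromosomes of NUP170, LYS2 and STH1 came from a table of the R64 assembly, and no coordinate of it was used, since the build of the files is unnamed. A reference sequence was not used here. The measures fixed before the data were examined were set on windows at start codons and on gene lists, and these could not be run. They were replaced, after the files had been seen, by depleted regions: stretches of 80 to 400 bp between the edges of neighbouring calls in a library outside the comparison (0 h calls for the nup170 comparison, wild-type calls for the Sth1 comparison, nup170 deletion calls between the controls). Taking the regions from another library keeps counting error of the compared libraries out of their choice. The gene lists, base composition corrections and tests of unique placement were not analysed here.

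Each read was moved 73 bp from its end towards the nucleosome centre, and reads were counted in regions. Ratios are log2 ratios of reads scaled by library total, with 0.5 reads added to each count, so ratios of low counts are pulled towards 0. Regions with at least 50 reads over both libraries were tested against a 2-fold threshold, and 100 binomial draws of the pooled counts gave the number that counting error alone would pass. The rule for named regions, adapted from the rule for genes fixed before the data were examined, takes the 10 highest and the 10 lowest ratios per comparison, leaving out regions within 2 kb of the deleted stretches; blocks and other regions in the text were chosen after their values were seen. Intervals of single ratios are exact binomial 95% intervals, shares have Wilson 95% intervals, and means, medians and pooled densities over regions have percentile bootstrap intervals. Regions are not replicates, and no p-value was computed because each group has 1 library.

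Chromosome ends were approximated by the outermost read in any library, and regions within 25 kb were taken as near an end. A list median was ranked among 10000 random lists of the same size matched on deciles of occupancy, and calls near the ends were ranked among calls matched on score deciles. Members were drawn singly over the genome, so these percentiles ignore that neighbouring regions and calls can vary together. Arms were summarised as the log2 ratio of the outermost 25 kb minus that from 25 to 100 kb, and interior stretches of the same layout gave the random sets. Shared calls lie within 20 bp of each other, and missing calls have no counterpart within 73 bp; 100 random circular shifts gave the chance share. Bordering density is the read density within 20 bp of the call at each edge of a depleted region, relative to the 2 kb around the region, where the next call out lies 140 to 200 bp away; linker density was taken midway to that call. The bordering density, the distance between bordering calls, the summary per arm and the count of calls missing in both perturbed libraries were chosen after the files had been seen, and the bordering density was added after the mean profiles had been seen, first in pooled form and then as the median over calls, when both forms and the values of the controls were known.

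Alternatives were scaling by the median 1 kb window or by the surrounding 20 kb, a shift by the fragment length of each library, reads per position capped at 61 in wild type, 104 in the nup170 deletion, 58 at 0 h and 55 at 2 h, all libraries thinned to 10971197 reads, no minimum, wider regions or gaps, 10 kb in place of 25 kb, calls within 40 bp, the upper part of the scores, and the 0 h library as control. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The measures were tested on simulated data. Regions planted with a 4-fold change were drawn only from those with at least 100 reads over both libraries. The simulated noise was counting error alone. In the nup170 comparison (11334 regions), 100% of 200 planted regions were recovered and 7 unchanged regions passed 2-fold. In the Sth1 comparison (10549 regions) the values were 100% and 8. Recovery of regions with fewer reads was not tested. Of 100 lists without a shift, 9 fell outside the central 95% in each of these comparisons. A planted change in distance of −4.87 bp came back as −4.61 bp for nup170 and one of −4.99 bp as −4.81 bp for Sth1. Bordering densities planted at 1.88 and 1.46 came back as 1.88 and 1.45 for nup170 and as 1.88 and 1.45 for Sth1, and independent simulated losses overlapped by 0.997 and 0.932 times the matched draws.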

Results

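Mononucleosomal DNA from budding yeast was sequenced in 4 libraries, 1 per group. Cells had been fixed with formaldehyde and digested with micrococcal nuclease (MNase), which cuts linker DNA and leaves nucleosomal DNA, so that each read end marks the edge of a protected fragment. The groups were a wild-type strain, a strain lacking NUP170, and cells of an Sth1 depletion strain at 0 h and 2 h of depletion. Nup170 is a nucleoporin of the nuclear pore complex, and Sth1 is the ATPase of the RSC chromatin remodeller. The wild-type library held 10971197 reads, the nup170 deletion library 12680549, the 0 h library 28492505 and the 2 h library 26409786. The distance between the strands gave a typical fragment of 149 bp in wild type, 141 bp in the nup170 deletion, 143 bp at 0 h and 131 bp at 2 h, so each perturbed library had shorter fragments than its control. The deposited nucleosome calls numbered 60582 in wild type, 57732 in the nup170 deletion, 59875 at 0 h and 56954 at 2 h, with median spacings of 169, 172, 170 and 175 bp. Neighbouring calls left a gap of 80 bp or more in 18.1% of cases in wild type and 24.2% in the nup170 deletion, and in 19.5% at 0 h and 24.4% at 2 h. Reads were spread least evenly in the nup170 deletion library, where the median 1 kb window held 0.546 times the mean, against 0.881 in wild type, 1.00 at 0 h and 0.969 at 2 h. There were no replicates, so every difference is between 2 libraries, no p-value is given, and intervals cover counting error or the spread over regions, which are not replicates.

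The genotypes were checked from stretches without reads. On chromosome 2, the nup170 deletion library had no read from position 75254 to 79805 (4552 bp), where wild type had 3788 reads, the 0 h library 10329 and the 2 h library 9522; a count of 0 allows up to 3 reads. NUP170 (YBL079W) is a gene of 4509 bp on chromosome II in the R64 assembly. A stretch of 4570 bp further along chromosome 2, from 469698 to 474267, had no read in wild type or the nup170 deletion and 12333 and 12299 reads at 0 h and 2 h. The labels give a lys2 deletion for the strains without reads there, and LYS2 (YBR115C) spans 4179 bp on the same chromosome. Loss of Sth1 protein leaves no trace in DNA and was not checked. Chromosome 9 stood apart in both libraries of the Sth1 depletion strain, with a median read density of 2.05 times the library median at 0 h and 2.14 times at 2 h, whereas the other 15 chromosomes lay between 0.943 and 1.04 at 0 h and between 0.926 and 1.07 at 2 h.

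**Figure D1:**
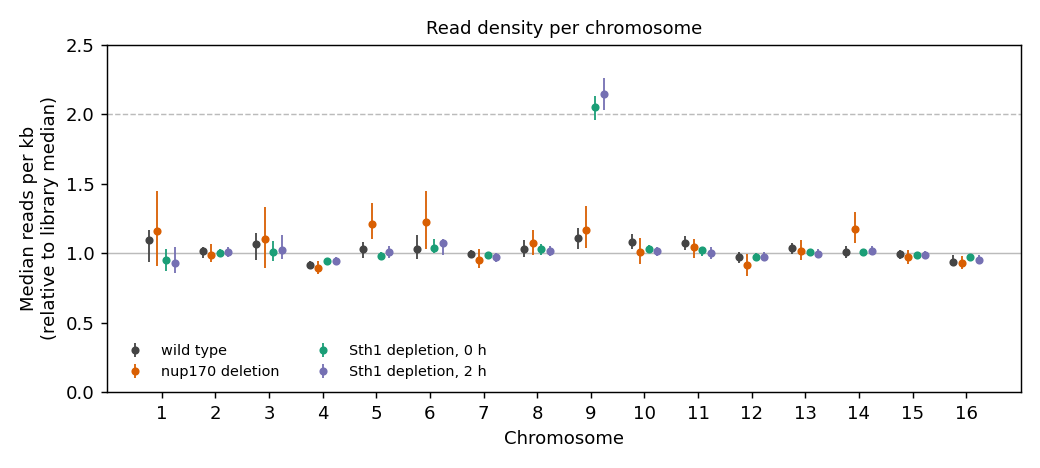
Median reads per kb of each of the 16 chromosomes relative to the library median (vertical axis), for the 4 libraries; points are medians over 1 kb windows and bars are 95% bootstrap intervals over windows. Chromosome 9 lies at 2.05 and 2.14 in the libraries of the Sth1 depletion strain, and at 1.11 in wild type and 1.17 in the nup170 deletion.

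The first comparison asked how nucleosomes differ without Nup170, above all near chromosome ends. Depleted regions are the stretches of 80 to 400 bp between neighbouring calls, here of the 0 h library. Read density at the calls bordering them was lower, relative to the surroundings, in the nup170 deletion library. The measure cannot tell fewer nucleosomes from nucleosomes shifted or spread away from the 0 h positions. The density within 20 bp of a bordering call had a median of 1.27 times the mean of the surrounding 2 kb (95% bootstrap interval 1.24 to 1.30), against 1.82 (1.78 to 1.86) in wild type, over 13696 bordering calls. It was lower in the deletion library at 8899 of 13695 bordering calls (65.0%), compared with 55.5% for 0 h against wild type, scored at nup170 deletion calls. The linkers beyond these calls held more reads, with a pooled density of 0.350 (0.334 to 0.367) against 0.256 (0.246 to 0.269) in wild type, but the control libraries differed by more, with 0.426 at 0 h and 0.235 in wild type. At bordering calls within 25 kb of a chromosome end the median was 1.43 (1.22 to 1.57) against 2.03 (1.81 to 2.30), so the difference was present both near the ends and over the genome. Between the control libraries (0 h and wild type) the median was 1.98 in each, measured at other positions, those of the nup170 deletion calls. Those calls come from a perturbed library, whereas the 0 h calls used above come from an unperturbed one and may favour wild type. Neither the 55.5% nor the equal medians are thus a matched baseline. The pooled density over all bordering calls, however, was 3.06 in wild type and 2.32 at 0 h, a difference as large as that between wild type and the deletion, 2.91 and 2.19. The pooled density was the first form of this measure; the median was made the main value after both had been seen, including that the control libraries were equal on the median and not on the pooled value, so this choice is exploratory.

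Depleted regions themselves held fewer reads in the nup170 deletion library. Of 4680 regions with at least 50 reads, 2516 were lower by 2-fold or more and 581 higher, where counting error alone gave means of 5.64 and 7.11. The median log2 ratio was −1.09 (interquartile range −1.72 to −0.26). Scaling by the median 1 kb window in place of total reads, which differs by −0.66 on the log2 scale in these libraries, gave a median of −0.43. It left 1278 lower and 812 higher, and the share of higher regions among those past 2-fold went from 18.8% to 38.9%. Between the control libraries, 3632 of 9365 regions were higher at 0 h than in wild type by 2-fold or more and 341 lower. Their median log2 ratio was 0.67, so many regions passed 2-fold without the deletion too. Pooled over all depleted regions, the density inside was 0.242 (0.225 to 0.262) times that of the surrounding 2 kb in the deletion library and 0.283 (0.273 to 0.294) in wild type. A call centre lay inside 29.7% of 11334 regions in the deletion (Wilson 95% interval 28.9% to 30.6%) and inside 38.8% (37.9% to 39.7%) in wild type. The distance between the bordering calls was greater by 1.43 bp on average in the deletion (0.96 to 1.92, 6074 regions) and by 3.34 bp (1.41 to 5.31, 391 regions) within 25 kb of an end. Measured from reads, the change was 1.35 bp (0.87 to 1.83), and near the ends 1.63 bp with an interval that held 0 (−0.38 to 3.65, 206 regions). The control libraries differed by more, −3.12 bp from calls and −1.86 bp from reads. With gaps of at least 120 bp the mean change was 0.50 bp, with an interval from −0.09 to 1.02 that held 0.

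**Figure D2:**
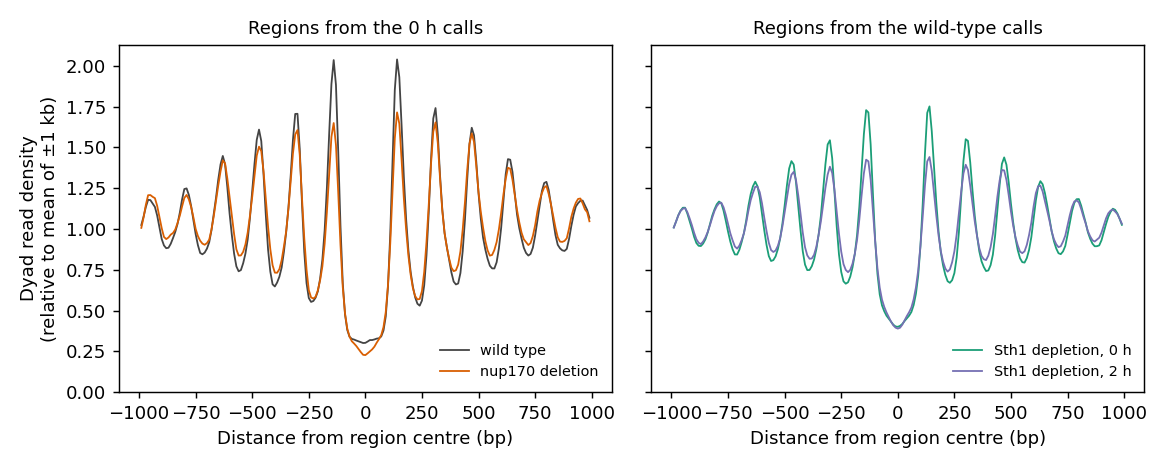
Read density at nucleosome centres (vertical axis, relative to the mean within 1 kb) against distance in bp from the centre of depleted regions, with reads per position capped and smoothed over 21 bp; the left panel sets the nup170 deletion against wild type and the right panel Sth1 depletion at 2 h against 0 h. The first peak stands at 1.72 in the nup170 deletion and 2.05 in wild type, and at 1.45 at 2 h and 1.76 at 0 h.

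Read density at chromosome ends was lower in the nup170 deletion library than in wild type. The log2 ratio was −0.67 within 5 kb of an end, −0.62 from 5 to 10 kb and −0.68 from 10 to 15 kb, then −0.09 and −0.02 in the next bins of 5 kb, 0.15 from 25 to 50 kb and 0.24 from 50 to 100 kb. Relative to the stretch from 25 to 100 kb of the same arm, the outermost 25 kb was lower on 29 of 32 arms, by a mean log2 ratio of −0.55 (−0.68 to −0.42), and the median over arms, −0.58, lay below the range of −0.19 to 0.11 that holds 95% of 10000 sets of 32 interior stretches. The control libraries differed in the same direction, with the 0 h library below wild type on 28 of 32 arms and a mean of −0.30 (−0.40 to −0.19). For the outermost 10 kb the control difference was as large, with means of −0.87 for the deletion and −0.90 for 0 h, each against wild type. Set against the 0 h library, the deletion library was lower on 20 of 32 arms, with a mean of −0.25 (−0.41 to −0.10), and for the outermost 10 kb the mean was 0.03 (−0.23 to 0.24). By distance, it was higher than the 0 h library within 5 kb of an end (0.51) and lower from 5 to 10 kb (−0.26) and from 10 to 15 kb (−0.59), so the direction within 5 kb depended on the control. In the next bins of 5 kb it was −0.02 and 0.01 against 0 h. It was 0.12 from 25 to 50 kb and 0.24 from 50 to 100 kb, the stretch that the arm mean is relative to. Depleted regions within 25 kb of an end did not stand apart from others in the main setting: their median log2 ratio of −1.08 (302 regions) lay at percentile 27.6 of random lists matched on occupancy. Scaling by the median 1 kb window made the median −0.42, but it shifts all regions alike and cannot change the percentile. Other settings changed that rank, to percentile 0.01 with regions widened by 50 bp and 99.99 with scaling by the surrounding 20 kb.

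**Figure D3:**
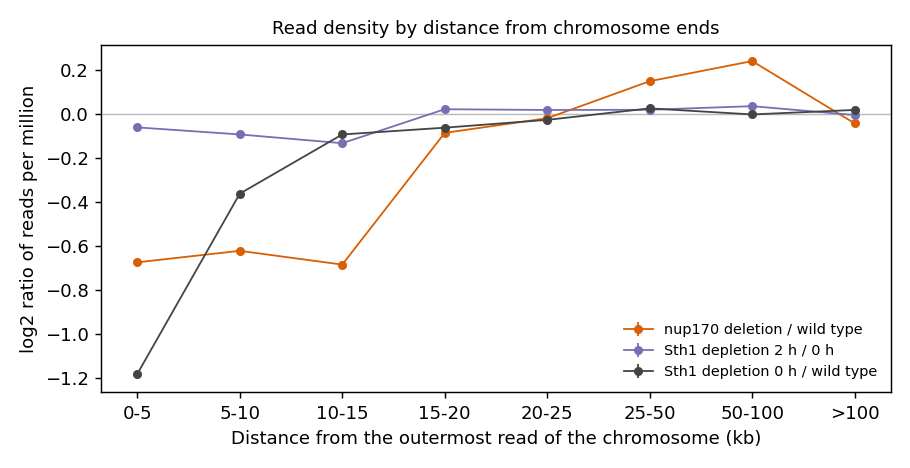
Log2 ratio of reads scaled by library total (vertical axis) in bins of distance in kb from the outermost read of each chromosome, for 3 pairs of libraries; bars are 95% counting intervals, mostly smaller than the points. The nup170 deletion lies at −0.67 within 5 kb and 0.24 from 50 to 100 kb, Sth1 depletion stays between −0.13 and 0.03, and the control libraries differ by −1.18 within 5 kb.

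Nucleosome positions were largely shared between the nup170 deletion and wild type. A deletion call lay within 20 bp of 75.9% of wild-type calls (75.5% to 76.2%), where shifted calls gave 19.7%. No deletion call lay within 73 bp of 10.9% of wild-type calls (10.7% to 11.2%). Within 25 kb of the ends, 73.5% of 3283 calls were shared and 12.8% had no counterpart, against 75.1% and 11.4% in random calls matched on score (percentiles 0.9 and 99.7). The random calls were scattered and those near the ends are neighbours, so these percentiles may overstate how far the ends stand apart. The control libraries, set against each other in the same way, shared 76.8% of calls, with 71.9% near the ends (76.1% when matched).

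The 10 depleted regions with the highest ratios in the nup170 comparison each held 58 to 105 reads in the deletion library and none in wild type. On chromosome 7 from 197532 to 197641, 105 reads against 0 made the deletion at least 30.3-fold higher (0 counts taken as the floor of 3 reads). On chromosome 8 from 505719 to 505872, 77 reads against 0 gave at least 22.2-fold, and on chromosome 3 from 78366 to 78611, 73 reads against 0 gave at least 21.1-fold. These floors leave out the counting error of the deletion's own reads; exact 95% intervals, which include it, start at log2 ratios of 4.60, 4.14 and 4.06. A deletion call was centred in 5 of these 10 regions and a wild-type call in 0. The 10 lowest regions ran from −4.39 to −3.58 on the log2 scale, and 9 of them held a wild-type call and 4 a deletion call. Calls and ratios rest on the same libraries, so these call counts follow from the ranking and are no separate support. The lowest was on chromosome 13 from 649716 to 649814, with 5 reads in the deletion and 99 in wild type (−4.39, exact 95% interval −6.17 to −3.25). Next was chromosome 11 from 373737 to 373993, with 6 and 86 reads (−3.94, −5.54 to −2.87). None of these 20 regions lay within 25 kb of an end. Over blocks of 20 kb, the highest ratio was on chromosome 11 from 520001 to 540000 (1.23) and the lowest on chromosome 12 from 680001 to 700000 (−1.31), where the 0 h library differed from wild type by −0.10 and 0.11. Regions without wild-type reads also headed the comparison of the controls, where the 10 highest held 105 to 179 reads at 0 h and none in wild type. Such ratios against this wild-type library thus also arose without the deletion.

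The second comparison asked how nucleosomes differ after 2 h of Sth1 depletion. Read density at the calls bordering depleted regions, here those of wild type, was again lower relative to the surroundings. Its median was 1.49 (1.47 to 1.52) at 2 h against 1.93 (1.90 to 1.95) at 0 h over 13225 bordering calls. Nucleosomes shifted or spread away from the wild-type positions would also lower this density. In pooled form it was 1.75 at 2 h and 2.31 at 0 h, and the controls differed by as much (2.32 at 0 h and 3.06 in wild type). The density was lower at 2 h at 9907 of these calls (74.9%), compared with 55.5% for 0 h against wild type. The 55.5% was scored at nup170 deletion calls, so it is not a matched baseline. The wild-type calls used here come from an unperturbed library and may favour 0 h. Linkers beyond them had a pooled density of 0.548 (0.539 to 0.557) at 2 h against 0.416 (0.409 to 0.424), and the next calls out 2.10 (2.05 to 2.18) against 2.45 (2.40 to 2.52). The control libraries differed by more on both, with linkers at 0.426 at 0 h and 0.235 in wild type and next calls at 2.42 and 3.44. Within 25 kb of the ends the median at bordering calls was 1.58 (1.42 to 1.69) against 1.95 (1.82 to 2.05). The distance between bordering calls was shorter by a mean change of −2.07 bp (−2.47 to −1.64, 5288 regions), with 28.9% of regions narrower by 10 bp or more and 18.4% wider. Measured from the reads in place of the calls, the change was −0.30 bp (−0.50 to −0.11), and the control libraries, 0 h against wild type, differed by more (−3.12 bp from calls, −1.86 bp from reads).

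Reads inside depleted regions differed little in sum at 2 h. Of 7473 regions, 589 were higher by 2-fold or more and 256 lower, where counting error gave means of 3.82 and 4.08, and the median log2 ratio was −0.00 (interquartile range −0.39 to 0.42). Regions widened by 50 bp on each side gave 218 higher and 279 lower. The pooled density inside was 0.419 (0.407 to 0.432) times the surroundings at 2 h and 0.407 (0.398 to 0.418) at 0 h. Near the ends, the median over 436 regions was 0.03, at percentile 88.9 of matched lists. It lay above the central 95% of lists with scaling by the surrounding 20 kb (0.10, percentile 99.8) and with thinned libraries (0.052), and below 0 within 10 kb of an end (−0.05, percentile 39.1). Chromosome arms showed a mean log2 ratio at the outermost 25 kb of −0.05 (−0.09 to 0.00), with 22 of 32 arms lower; the median over arms, −0.07, lay below the range of −0.04 to 0.03 for interior stretches. Calls were shared for 81.6% of the 0 h calls (81.3% to 81.9%, chance 19.4%), and 8.16% had no counterpart within 73 bp. Near the ends, 79.1% of calls were shared, against 77.5% when matched on score (percentile 99.1, with the same limit as for nup170).

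Among the 10 regions highest at 2 h, chromosome 7 from 639564 to 639681 held 46 reads at 2 h and 6 at 0 h (2.95, exact 95% interval 1.82 to 4.57). The deepest were chromosome 9 from 222633 to 222841, with 353 and 76 reads (2.32, 1.96 to 2.70) on the chromosome of raised density in both libraries, and chromosome 5 from 474039 to 474173, with 277 and 49 (2.60, 2.17 to 3.08). The 10 lowest ran from −2.03 to −1.72, and 3 of them lay within 25 kb of an end. They included chromosome 10 from 251713 to 251821, with 11 reads at 2 h and 50 at 0 h (−2.03, −3.17 to −1.11), and chromosome 4 from 1520798 to 1520927, 4.60 kb from the end, with 31 and 129 (−1.93, −2.56 to −1.37).

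The perturbations were then compared with each other, with no library in common. Log2 ratios of reads per kb correlated across 11585 windows of 1 kb (Pearson r = 0.670, Spearman rho = 0.678) and across 595 blocks of 20 kb (r = 0.737, rho = 0.736). These are correlations across windows of the genome, which are not independent replicates. Each perturbed library had shorter fragments than its control, so the correlations cannot separate a shared effect of the perturbations from stronger digestion. Ratios varied more in the nup170 comparison (SD 0.465 over 20 kb blocks) than in the Sth1 comparison (SD 0.0953). The block on chromosome 12 from 1040001 to 1060000 was among the lowest in both, at −1.30 and −0.35. Of 46548 calls common to wild type and 0 h, 2878 were missing in the nup170 deletion (6.18%), 2618 at 2 h (5.62%) and 763 in both, where draws matched on the scores in both controls gave a mean of 278 and at most 336.

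**Figure D4:**
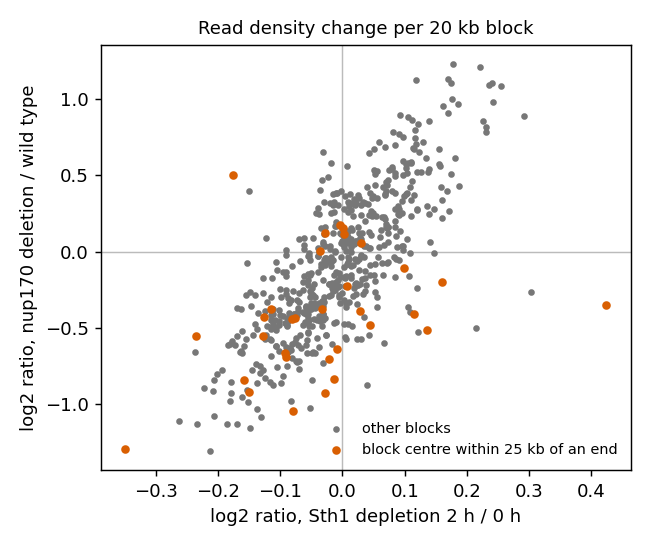
Log2 ratio of reads scaled by library total in 595 blocks of 20 kb, Sth1 depletion at 2 h over 0 h (horizontal axis) against the nup170 deletion over wild type (vertical axis); each point is a block, and blocks centred within 25 kb of an end are marked. The ratios rise together (Pearson r = 0.737 across blocks).

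Between the control libraries, depleted regions differed more than in the Sth1 comparison. Of 9365 regions, 3632 were higher at 0 h than in wild type by 2-fold or more and 341 lower, with a median log2 ratio of 0.67, or 3302 and 414 after scaling by the median 1 kb window. The higher read density of chromosome 9 at 0 h enters this comparison, with blocks of 20 kb there from 0.42 to 1.23, and 4 of the 10 highest regions lie on it. Scaling by the surrounding 20 kb gave 3475 higher and 336 lower. Near the ends the median of 530 regions was 0.50, at percentile 0 of matched lists, but 0.66 at percentile 44.3 with that scaling. The strains differ in more than the perturbation, and whether libraries were prepared together is not given in the sources used here.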

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

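The tests in this part were chosen after the read density of chromosome 9 had been seen. Whole-chromosome density cancels within the nup170 and Sth1 comparisons to the extent that the compared libraries share it, and it enters the comparison of 0 h with wild type (1.11): chromosome 9 lay at 2.05 times the library median at 0 h of Sth1 depletion and at 2.14 times at 2 h. Heavily read positions would raise few stretches, but 20 of the 21 blocks of 20 kb on the chromosome lay at or above 1.5 times the median in both libraries. A trend with base composition or digestion would raise blocks elsewhere too, but at most 3 of 574 blocks on other chromosomes reached that level in either library. An additional copy of chromosome 9 in this strain is a candidate explanation that the values allow, with a density of 2.05 in the 0 h library and the other 15 chromosomes between 0.926 and 1.07 in both. STH1 (YIL126W) lies on chromosome IX, and whether the copy number is linked to the depletion strain's construction was not tested.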

How the results depend on the processing

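Settings applied only to the replacement measures (wider regions or gaps, local scaling, the 0 h control, pooled densities, distances from reads) were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and splits of samples need more libraries. Base composition, unique placement, start-codon windows and gene-array shifts were not run, since a reference sequence of the files' build was not used here. A count was held to have moved past a 1.5-fold difference, a subtelomeric median to be weaker or stronger where its percentile crossed the central 95%, and other values to have moved outside their 95% interval; 43 alternative values moved, 4 were stronger, 1 was weaker and 111 stayed within these limits. A subtelomeric median can thus shift and keep its percentile, as with scaling by the median 1 kb window for nup170 (−0.42). None of these alternatives turned the sign of a called value, though the uncalled subtelomeric median for Sth1 went from 0.034 to −0.047 within 10 kb of an end. Beyond them, with 0 h as control, the nup170 arm mean for the outermost 10 kb went from −0.87 to 0.025 and the bin within 5 kb from −0.67 to 0.51. Causes were not tested unless stated. Scaling by the median 1 kb window gave 1278 lower regions in the nup170 comparison. With at least 1 read in each library in place of the minimum over both, more regions were tested. The higher and lower counts were 1148 and 4306 for nup170, 944 and 611 for Sth1, and 822 lower between the controls. That setting leaves out regions without a read in 1 library, such as the highest named regions of the nup170 comparison. Widening regions by 50 bp gave 1088 higher for nup170, 218 higher for Sth1 against 279 lower, which turned the balance of that comparison, a subtelomeric median of −1.03 for nup170 at percentile 0.01, and inside densities of 0.360 in wild type, 0.344 in the nup170 deletion, 0.542 at 0 h and 0.562 at 2 h. Local scaling gave subtelomeric medians of −0.59 for nup170 (percentile 99.99), 0.10 for Sth1 (99.8) and 0.66 between controls (44.3); it removes the trend along the arm by construction, so the nup170 list moved from within to above the matched lists. Thinning, which tests fewer regions, left 320 higher for Sth1, a correlation over 1 kb windows of 0.658, and, thinned to the shallowest library, a subtelomeric median log2 of 0.052 for Sth1, above its matched lists. Gaps of at least 120 bp gave 169 lower for Sth1, an inside density of 0.225 in the nup170 deletion, distances of 0.50 bp for nup170 and −2.55 bp between controls, and bordering densities of 1.86 and 1.32 in wild type and the nup170 deletion, 1.96 and 1.55 at 0 h and 2 h, and 2.05 and 2.01 for wild type and 0 h. Pooled bordering densities were 2.91 and 2.19, 2.31 and 1.75, and 3.06 and 2.32 in the same order. The outermost 10 kb gave arm means of −0.87 for nup170 and −0.90 between controls, and the 0 h library as control gave −0.25. Distances from reads were −0.30 bp for Sth1 and −1.86 bp between controls, and with calls in the upper part of the scores they were −2.61 and −4.07 bp. Calls shared within 40 bp came to 85.2%, 89.3% and 87.1% for nup170, Sth1 and the controls, and among calls of higher score to 66.1%, 72.6% and 64.8%. The wild-type depth of 10971197 reads limits single regions, where a count of 0 allows up to 3 reads.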

Other observations

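In this part, the test on block trends for calls missing in both perturbed libraries was chosen before its result was seen, and the other tests were chosen after. The 763 calls missing in both the nup170 deletion and 2 h of Sth1 depletion had lower scores, with a median wild-type score of 45.4 against 115 for the 41815 calls kept in both. They were near a chromosome end in 6.68% of cases against 4.86% of kept calls, but so were calls missing only at 2 h (7.71%) or only in the deletion (6.29%).

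Calls missing in both libraries were more numerous than separate losses would give. Low scores alone would give too few, since the number was 2.74 times the mean of draws matched on deciles of the scores in both controls, above the highest draw of 336. What the score measures is not given, so weakness or spread of a call that it does not capture stays open. A trend in read density over 20 kb blocks left the same ratio of 2.74 after matching on it, with 753 calls and a mean of 274 in draws. Scores were matched in coarser classes in that test. Base composition at the call itself also stays open, as does stronger digestion in both perturbed libraries, whose fragments of 141 and 131 bp were shorter than those of their controls (149 and 143 bp). A set of nucleosomes that both Nup170 and RSC help to keep in place may contribute, but these libraries cannot separate it from digestion.

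A wild-type library high at the ends could explain the lower read density at chromosome ends in the nup170 deletion library. This was tested with the 0 h library as control. For the outermost 25 kb the mean stayed below 0 at −0.25 (−0.41 to −0.10), against −0.55 with wild type. This mean is relative to 25 to 100 kb of the arm, where the deletion library itself lay above 0 h (0.12 and 0.24). The mean alone therefore cannot tell low ends from a high reference stretch. Scaled by library total, the deletion library lay below 0 h from 5 to 10 kb (−0.26) and from 10 to 15 kb (−0.59). Within 5 kb it lay above 0 h (0.51), and from 15 to 25 kb it was −0.02 and 0.01. The mean thus mixed a high reference stretch with low density in only some bins near the ends. How much of the difference the wild-type library accounts for stays open. For a wild-type library that is high at chromosome ends, outermost 10 kb, the mean was 0.025 (−0.23 to 0.24), but this mean covers opposite bins, higher than 0 h within 5 kb (0.51) and lower from 5 to 10 kb (−0.26). The wild-type library could thus account for the difference within 5 kb, and 5 to 10 kb stays open. From 10 to 15 kb the deletion library was lower against both controls, at −0.68 against wild type and −0.59 against 0 h. The control libraries differed by −0.09 there, so the lower density in that bin did not depend on the control. The 0 h strain also differs otherwise, and each group has 1 library. A trend shared with the Sth1 comparison cannot be told apart. The 24 blocks centred within 20 kb of an end had a mean of −0.44 (−0.59 to −0.29) against wild type before adjustment. After least squares on the Sth1 ratios their mean was −0.31 (−0.54 to −0.07). With the regression reversed it was −0.30 (−0.68 to 0.04), an interval that held 0. An effect of Nup170 on chromatin near the ends, the subject of the series, stays open and needs replicate libraries.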
